A study of Mus musculus with 10 samples.

How the data were processed

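RNA of sorted cardiomyocytes from 5 Sprr1a-GFP mice was sequenced, 1 GFP+ and 1 GFP− library per mouse. Per the labels' protocols, total RNA was isolated with a column kit for small samples, copied and amplified with SMARTer chemistry, and made into libraries with Nextera XT, a transposase kit that does not mark strand. No molecular identifiers are named, so PCR copies cannot be told from separate molecules. The deposited values are whole-number read counts per gene, not normalized, in 1 table for all 10 libraries. The submitters' processing notes name fastp 0.23.1, STAR 2.7.9a, Subread 2.0.1 and featureCounts and the mouse genome build GRCm39. The annotation release, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. Overlapping genes, antisense genes and genes with near-identical copies (Sprr2 genes, tubulins, ribosomal protein genes, mitochondrial genes with nuclear copies) are therefore uncertain. Genes are named by the symbols in the table, which gives no positions, and genome coordinates were not used here.

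The table has 56832 genes, of which 30691 are at 0 in all libraries and 1544 carry only an identifier in place of a symbol. Libraries were compared for identical values, and 0 pairs were identical. Groups and mouse identifiers were taken from the titles and the cell type labels. Libraries of the same mouse are pairs because they carry the same animal identifier. As a check, the deviations of same-mouse libraries from their group means correlated across genes with r = 0.292 (17C1), 0.397 (17C2), 0.161 (21A4), 0.0741 (21A5) and 0.637 (21A7). The GFP+ libraries of 17C1, 17C2, 21A4 and 21A7 correlated best with the GFP− library of their own mouse. Of the GFP− libraries, those of 17C2 and 21A7 did so with their GFP+ library and those of 17C1, 21A4 and 21A5 did not. For 21A5 neither library did. However, both of its libraries had 0 counts of Xist and counts of the Y-linked Ddx3y (684 in GFP−, 372 in GFP+). Every other library had Xist counts and 0 of Ddx3y. The pairing of 21A5 therefore rests on the identifier and on these sex-linked genes. Before the data were examined, the unpaired fit was set as the primary one, the fit with the mouse as a block as an alternative, and the gene lists and the rule for naming genes were fixed.

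Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, two-sided, TMM factors, low counts removed with filterByExpr, which left 12115 genes, Benjamini-Hochberg adjusted p under 0.05). Standard errors are the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM values a prior count of 2. From 36 lists, 33 had at least 5 tested genes (the neutrophil, lymphocyte and red cell lists did not). They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation, camera on ranks and the rotation test fry, which asks whether the genes of a list move on balance one way. Older symbols were matched by synonym in a RefSeq table of the earlier mouse build, used for names only. List medians are given relative to the median log2 fold change of all tested genes (−0.07 unpaired, −0.04 paired). This relative scale was adopted after list medians were seen to change sign with the scaling.

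The rule named Sprr1a and the preset genes Nppa, Nppb, Myh7, Myh6, Acta1, Ankrd1, Xirp2, Flnc, Clu, Atp2a2, Ppargc1a and Cpt1b. It also named up to 10 genes in each direction with the largest change among those past the threshold, with a mean of at least 10 CPM, the same direction in all 5 mice and a name other than a gene model or clone. For each list it named up to 3 genes with the smallest adjusted p and 1 or 2 that did not pass. After the data were seen, the same rule was applied to the paired fit, and the keratin and second-list mesothelial genes in the closing part were added. The result of 1 gene that the rule names is not reported here.

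Alternatives were DESeq2 1.42.0 (Wald test), limma voom with sample quality weights, DESeq2 size factors, library size alone, no filter or a stricter filter on low counts (5 CPM in 5 libraries), removal of mitochondrial genes, the identifier series as a covariate, each series alone, and each mouse or library left out in turn. Chosen after seeing the data were the removal of mitochondrial genes with 5 abundant loci, a score of fibroblast, macrophage, endothelial and mural markers as a covariate, scaling to the sarcomere genes, and all alternatives of the paired fit. Library measures were compared with an exact permutation test over 252 regroupings, whose smallest p is 0.00794, and with exact sign flips within mice, whose smallest p is 0.0625.

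Total counts were 12244373 to 38879965 per library, but only 2217409 to 14074075 lie outside mitochondrial genes and 5 abundant loci, which sets the precision for low genes. The fits were tested on simulated counts for the 12115 genes with 200 changed genes. The unpaired fit recovered 0% of genes changed 2-fold, 6% of 4-fold, 50% of 8-fold and 66% of 16-fold changes with 0 false calls. The paired fit recovered 4%, 58%, 82% and 84%, with 4 false calls. The simulation used the dispersions of the paired fit and mouse effects shared fully by both libraries of a mouse. These effects were permuted over genes, and the changes were the same in both series of mice. This setting favours the paired fit, so its rates do not carry over to the real libraries.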

Results

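Transcript levels were measured in heart muscle cells of Sprr1a-GFP mice, a reporter strain whose green fluorescent protein is named for Sprr1a. The titles of all 10 libraries carry the tag Hetz, read here as heterozygous. Hearts were taken 5 days after a myocardial infarction made at 12 weeks of age. Cells freed by perfusing the heart with enzyme were sorted into GFP+ cells, which the labels call border zone cardiomyocytes, and GFP− cells, which they call remote zone cardiomyocytes. Each of 5 mice gave 1 library of each kind, so the 10 libraries form 5 pairs. By their counts of Xist and the Y-linked Ddx3y, mouse 21A5 was male and the others were female. The mouse identifiers fall into a 17C series (17C1 and 17C2) and a 21A series (21A4, 21A5 and 21A7) with differently worded titles. Results within each series are therefore given beside the pooled ones, and where no series is named, passing or not passing refers to all 5 mice. Total counts per library lay between 12244373 and 38879965, and 12115 of 56832 genes had enough counts to be tested.

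The libraries differed widely in composition. Mitochondrially encoded genes took 9.20% of counts in the GFP− library of mouse 21A7 (95% Wilson interval 9.18 to 9.21) and 91.21% in the GFP+ library of the same mouse (91.20 to 91.22). These intervals cover counting error only. The share averaged 59.4% ± 22.4 (SD, n = 5) in GFP+ and 38.3% ± 22.1 in GFP− libraries, a difference within the spread (two-sided exact permutation p = 0.167; 0.389 after Benjamini-Hochberg adjustment over 7 library measures). After removal of these genes and of 5 abundant ribosomal or unnamed loci, 2217409 to 14074075 counts were left per library. Fibroblast genes held 0.0496% of the remaining counts in the GFP− library of 17C1 (95% Wilson interval 0.0477 to 0.0515) and 5.20% in that of 21A7 (5.19 to 5.22). Their share averaged 0.720% ± 0.852 (SD, n = 5) in GFP+ and 2.31% ± 2.28 in GFP− libraries (exact permutation p = 0.238, adjusted 0.417). The number of genes detected was 15186 ± 751 in GFP+ and 17219 ± 2206 in GFP− libraries (SD, n = 5; exact permutation p = 0.127, adjusted 0.389). It was lower in the GFP+ library in 5 of 5 mice (exact sign-flip p = 0.0625, the smallest that 5 pairs allow). In a fit chosen after seeing the data, a score of fibroblast, macrophage, endothelial and mural markers, called the non-myocyte score, entered as a covariate.

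**Figure D1:**
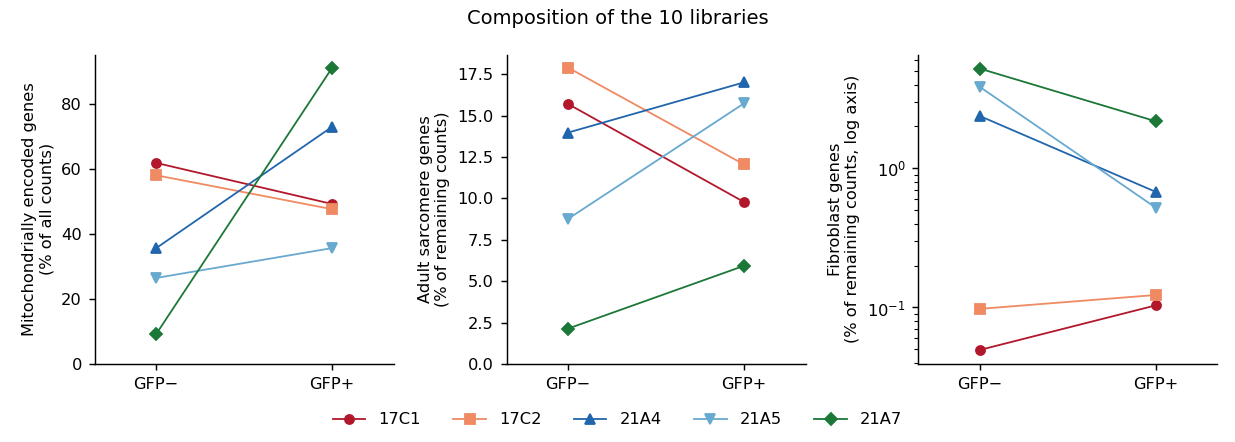
Share of mitochondrially encoded genes in all counts (left), and of adult sarcomere genes (middle) and fibroblast genes (right, log axis) in the counts left after removal of mitochondrial genes and 5 abundant loci, in percent, with 1 line per mouse joining its GFP− and GFP+ library. The fibroblast share was 2.37% or more in the 3 GFP− libraries of the 21A series and 0.0978% or less in the GFP− libraries of 17C1 and 17C2.

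The comparison of GFP+ with GFP− cells asked how Sprr1a-expressing border zone cardiomyocytes differ from remote cardiomyocytes of the same hearts. Sprr1a encodes a small proline-rich protein of the cornified envelope, and since it names the reporter it checks the sort. Its counts were 1452 to 6903 in GFP+ and 10 to 406 in GFP− libraries. This was 235 ± 70.5 against 3.44 ± 3.43 counts scaled to a common library size (CPM, SD, n = 5), a log2 fold change of 6.09 ± 0.86 (SE; edgeR quasi-likelihood adjusted p = 0.0283). Without pairing it was 6.35 in the 17C mice (adjusted p = 0.000853) and 5.999 in the 21A mice (0.203). With the mouse as a block Sprr1a passed in each series. Serpinb1a, an inhibitor of neutrophil serine proteases, rose by 5.65 ± 0.67 (adjusted p = 0.0249), from 4.42 ± 3.22 to 224 ± 95.5 CPM. Star, which carries cholesterol into mitochondria, rose by 3.46 ± 0.51, and Uchl1, a ubiquitin hydrolase, by 3.23 ± 0.43. Rtn4, a protein that shapes the endoplasmic reticulum, rose by 3.12 ± 0.47, from 52.6 ± 22.2 to 457 ± 182 CPM. Zfp697 rose by 2.61 ± 0.34, the prion protein gene Prnp by 1.90 ± 0.30 and Pfkp, a phosphofructokinase of glycolysis, by 1.89 ± 0.30. The edgeR adjusted p of these 6 genes lay between 0.0249 and 0.0466, and all 8 genes were higher in 5 of 5 mice.

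In all, 10 genes passed an adjusted p of 0.05, and all were higher in GFP+ cells. The other 2, Eppk1 (4.16 ± 0.55) and 2200002D01Rik (3.50 ± 0.49), fall outside the naming rule and were named after their values were seen. With edgeR 0 genes were lower, while 409 were lower at an unadjusted p under 0.05, and DESeq2 called 45 lower and limma voom 51. With the mouse as a block, which uses the pairing by animal, 104 genes passed, 83 higher and 21 lower, and all 10 were among them. Within the 17C mice 1059 genes passed without pairing (512 higher, 547 lower). Within the 21A mice 0 passed with edgeR (1621 at an unadjusted p under 0.05). With pairing these numbers were 1510 and 889. Of 100 paired calls that were tested in the 17C mice, 81 passed there with the same sign. The libraries of these mice are among those that gave the paired calls, so this overlap is not an independent check. Scaling by library totals alone gave 11 genes higher and 624 lower and moved the median of all genes to −1.24 on the log2 scale. Scaling to adult sarcomere genes, chosen after seeing the data, left 0 calls (527 at an unadjusted p under 0.05) with that median at −0.93. The count of 10 became 0 without the GFP− library of 17C2 or the GFP+ library of 17C1, 17C2, 21A4 or 21A5 (723 to 1056 at an unadjusted p under 0.05). It became 1 without the GFP− library of 17C1 or 21A4, and 34 without the GFP+ library of 21A7. When 1 mouse or 1 library was left out the Sprr1a log2 fold change lay between 5.75 and 6.85, with edgeR adjusted p from 0.0164 to 0.282. It passed without mouse 21A7, its GFP+ library or the GFP− library of 21A4 or 21A5. It did not pass without mouse 17C1 (0.236), 17C2 (0.282), 21A4 (0.153) or 21A5 (0.0871), nor without any other single library (0.0501 to 0.105). The paired count was 173 without 17C1, 0 without 17C2 (1492 at an unadjusted p under 0.05), 1 without 21A4, 6 without 21A5 and 71 without 21A7.

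**Figure D2:**
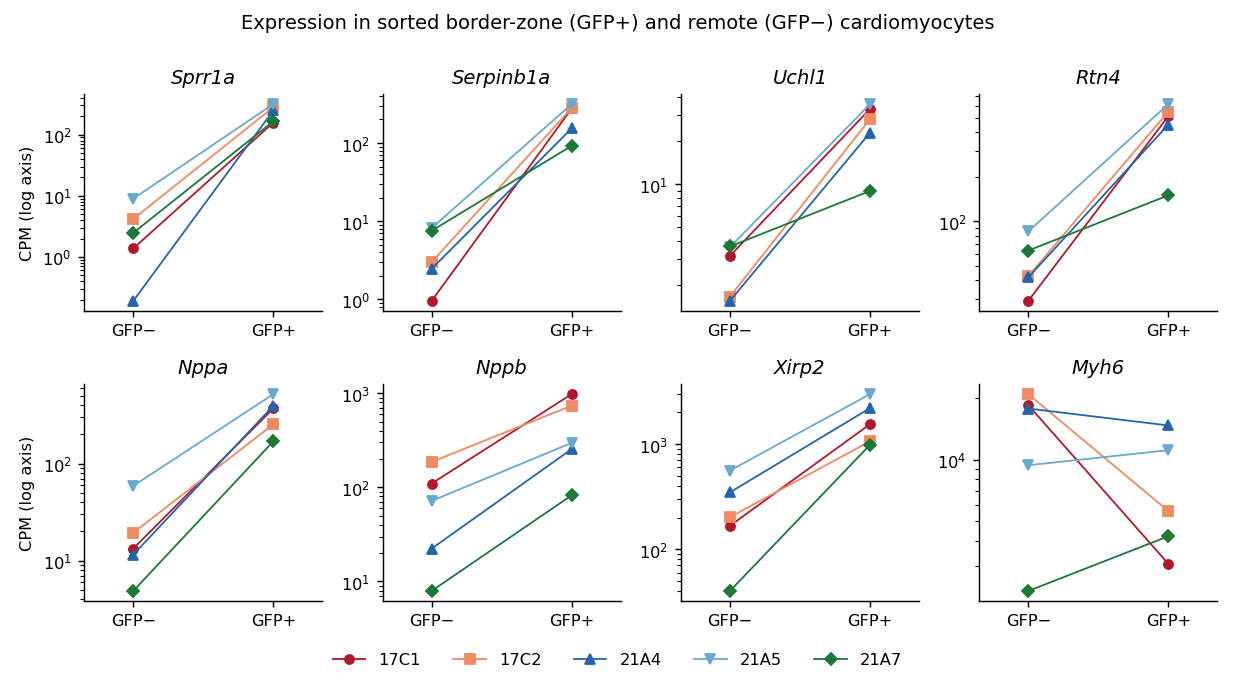
Levels of 8 genes in CPM (log axis, range set per gene) in the GFP− and GFP+ library of each of 5 mice, joined by a line per mouse. Sprr1a, Serpinb1a, Uchl1, Rtn4, Nppa, Nppb and Xirp2 were higher in the GFP+ library in 5 of 5 mice, and Myh6 in 2 of 5.

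Genes of the fetal and stress programme of cardiomyocytes stood higher in GFP+ cells. Nppa, which encodes atrial natriuretic peptide, reached 341 ± 134 CPM against 21.6 ± 21.5 (SD, n = 5). Its log2 fold change was 3.98 ± 0.66 (edgeR adjusted p = 0.0715), or 4.38 ± 0.40 with the mouse block (adjusted p = 0.0153). In the paired fit Nppb, the B-type natriuretic peptide, rose by 2.82 ± 0.35 (edgeR adjusted p = 0.0238; 0.442 unpaired). The secreted chaperone Clu rose by 2.98 ± 0.51 (0.0426; 0.0765 unpaired) and Ankrd1, a stretch-responsive repeat protein of the sarcomere, by 1.94 ± 0.32 (0.0424; 0.305 unpaired). Skeletal actin Acta1 (paired 3.08 ± 0.65, adjusted p = 0.0776) and Myh7, the slow myosin heavy chain (1.29 ± 0.53, 0.299), did not pass in either fit, although both were higher in 5 of 5 mice and Acta1 passed in the 17C mice (1.92, 0.0189). Of 16 tested genes of this list 1 passed unpaired and 6 paired, or 8 in each fit when adjusted over the list alone, all higher over the 5 mice. The list's median stood 1.21 above that of all tested genes (camera adjusted p = 4.70e-10; adjusted p = 0.0639 with an estimated correlation). With pairing it stood 1.60 above (adjusted p = 0.0383 with an estimated correlation), and it was 1.79 in the 17C and 0.84 in the 21A mice. In the 17C mice 9 members passed as higher and 2 as lower, the slow skeletal troponin Tnnt1 (−2.49, edgeR adjusted p = 0.0364) and the myosin heavy chain Myh7b (−2.90, 0.0405), both named after their values were seen. Over single omissions it passed each time, between 0.50 without the GFP− library of 17C1 and 1.65 without mouse 21A7. The mean rise per mouse was 1.59 ± 0.21 log2 units (SD, n = 5), between 1.39 and 1.89, and the rotation test fry passed in both fits (adjusted p = 0.0243 unpaired and 0.00168 paired). Relative to the sarcomere list, a scale chosen after seeing the data, the rise was not uniform. It was 2.84 in 17C1, 1.97 in 17C2, 1.11 in 21A4, 0.37 in 21A5 and −0.18 in 21A7 (mean 1.22 ± 1.21, SD, n = 5; exact sign-flip p = 0.125, 0.667 after adjustment over 32 lists). With all counts scaled to sarcomere genes the list's own median was 0.078, which is 1.00 above that of all genes. Other large paired changes were those of the fast skeletal troponin Tnnt3 (6.64 ± 0.88, edgeR adjusted p = 0.0251) and the epithelial keratin Krt18 (4.43 ± 0.70, 0.0376). Smooth muscle calponin Cnn1 rose by 3.85 ± 0.64 (0.0426), the stress cytokine Gdf15 by 3.49 ± 0.59 (0.0426) and the surface protein Cd24a by 3.29 ± 0.54 (0.0420). None of these 5 passed unpaired (adjusted p 0.0777 to 0.184).

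Genes of the intercalated disc and costamere, which tie muscle cells to each other and to the matrix, stood higher over the 5 mice and in the 21A series. The median of the adult sarcomere genes lay below that of all genes in the 17C series and above it in the 21A series. Xirp2, an actin-binding protein of the intercalated disc, reached 1757 ± 842 against 263 ± 199 CPM (paired log2 fold change 3.04 ± 0.44, edgeR adjusted p = 0.0345; 0.173 unpaired). The laminin receptor Itga7 rose by 1.58 ± 0.24 (0.0373; 0.321 unpaired). Desmin (Des, 2.49 ± 0.58, paired adjusted p = 0.100) and filamin C (Flnc, 1.29 ± 0.31, 0.114) did not pass, though Des passed in the 17C mice (1.27, 0.0306). Among 29 disc and costamere genes 0 passed unpaired and 2 paired, 1 and 10 when adjusted over the list alone. The list's median stood 0.55 above all genes (camera adjusted p = 0.000188; adjusted p = 0.655 with an estimated correlation), at −0.02 in the 17C (camera adjusted p = 0.403, 6 members higher and 3 lower) and 0.80 in the 21A mice (1.25e-06). Without the GFP+ library of 21A5 it was 0.28. Relative to the sarcomere list it was higher in 3 of 5 mice, with a mean of 0.99 in the 17C and −0.22 in the 21A mice. Myh6, the adult myosin heavy chain, had a log2 fold change of −0.83 ± 0.75 (adjusted p = 0.794), at −2.18 in the 17C (0.00319) and 0.05 in the 21A mice. The calcium pump gene Atp2a2 was at −0.80 ± 0.64 (0.764), with −1.62 in the 17C (0.00675) and 0.04 in the 21A mice. For 19 sarcomere genes the median stood 0.10 above all genes (camera adjusted p = 0.198). The list passed as lower in the 17C mice (−0.89, camera adjusted p = 0.000441, 8 members lower and 1 higher) and as higher in the 21A mice (1.04, 5.06e-05, 0 members higher). With an estimated correlation it passed in neither series (camera adjusted p = 0.677 and 0.655). With the preset correlation it also passed as higher without mouse 17C1 (0.47) or 17C2 (0.38), without the GFP− library of either (0.29 and 0.35) or without the GFP+ library of 21A7 (0.31). Without mouse 21A5 it was at −0.26, and with the non-myocyte score at −0.15, and did not pass. With pairing it stood 0.31 above (camera adjusted p = 0.0153; adjusted p = 0.836 with an estimated correlation). Pdlim5, a Z-disc adaptor, was the 1 paired call among them (1.46 ± 0.24, 0.0418; 0.503 unpaired), also when adjusted over the list alone. The median of 26 calcium handling and channel genes stood at −0.13 (camera adjusted p = 0.303). It passed as lower in the 17C mice (−0.97, 3.30e-08, 10 members lower) and as higher in the 21A mice (0.55, 0.0341). It was also lower with the non-myocyte score (−0.46, 0.000476), without mouse 21A5 (−0.32, 0.0348) or 21A7 (−0.21, 0.0269) and without the GFP− library of 21A7 (−0.41, 5.17e-05). When scaled to sarcomere genes its own median was −0.44, which is 0.48 above that of all genes, with a downward test (camera adjusted p = 0.106). Kcnj2, an inward rectifier channel, was lower in 5 of 5 mice without passing (−1.35 ± 0.52, 0.545), and passed in the 17C mice (−1.89, 0.00839).

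Over all 5 mice the median of glycolysis genes stood higher and that of fatty acid genes lower. The glycolysis list passed as higher in the 21A mice, with a median below 0 in the 17C mice, and the fatty acid list passed as lower in the 17C mice but not in the 21A mice. Besides Pfkp, the glucose transporter Slc2a1 rose in the paired fit (1.46 ± 0.26, edgeR adjusted p = 0.0479; 0.121 unpaired). Pgk1 was higher in 5 of 5 mice without passing (paired 1.12 ± 0.24, 0.0776), and passed in the 17C mice (0.97, 0.0311). Over 23 glycolysis genes 1 passed unpaired and 2 paired, 2 and 4 when adjusted over the list alone. Their median stood 0.35 above all genes (camera adjusted p = 0.000692; adjusted p = 0.655 with an estimated correlation), at −0.26 in the 17C (camera adjusted p = 0.996, 6 members higher and 4 lower) and 0.80 in the 21A mice (8.07e-06). With the non-myocyte score it was 0.033 and did not pass (0.124). Over single omissions it passed each time, between 0.11 without the GFP− library of 21A7 and 0.62 without mouse 17C1. Relative to the sarcomere list it was higher in 3 of 5 mice, with a mean of 0.82 in the 17C and −0.42 in the 21A mice. The median of 30 fatty acid uptake and oxidation genes stood at −0.90 (camera adjusted p = 7.01e-07; adjusted p = 0.674 with an estimated correlation). No member passed in either edgeR fit, and 0 unpaired and 1 paired did when adjusted over the list alone. The list stood at −1.56 in the 17C mice, where 24 members passed as lower, and at −0.28 in the 21A mice, with an upward test that did not pass (camera adjusted p = 0.966). When scaled to sarcomere genes its own median was −1.03, which is −0.10 relative to all genes (camera adjusted p = 5.64e-13). Acot2, a mitochondrial acyl-CoA thioesterase, was lower in 5 of 5 mice (paired −1.51 ± 0.32, 0.0776; −2.28 in the 17C mice, 0.00494). Ucp3 (−2.16 ± 0.76, 0.489), Ech1 (−1.60 ± 0.59, 0.513) and the coactivator Ppargc1a (−1.05 ± 0.62, 0.689) did not pass. All 3 passed as lower in the 17C mice (−3.95, −2.35 and −2.33, adjusted p 0.00167 to 0.00548). Cpt1b had 3 to 30 counts per library and was not tested. How reads of overlapping genes were counted is not given, so these counts may not reflect its level. Genes of the TCA cycle and branched-chain amino acid breakdown did not pass over all 5 mice (30 genes, median −0.26, camera adjusted p = 0.135). The list passed as lower in the 17C mice (−0.92, 8.78e-10, 12 members lower) and as higher in the 21A mice (0.26, 0.0416). It was also lower with the non-myocyte score (−0.65, 4.88e-06), with DESeq2 (−0.25, 0.0180), without mouse 21A5 (−0.43) or 21A7 (−0.34) and without the GFP− library of either (−0.39 and −0.57). When scaled to sarcomere genes its own median was −0.56, which is 0.37 above that of all genes, with a downward test (camera adjusted p = 0.0378). The nuclear-encoded respiratory chain did not pass over all 5 mice either (76 genes, −0.44, 0.130). It passed as lower in the 17C mice (−1.05, 6.31e-24, 50 members lower) and as higher in the 21A mice (0.45, 4.73e-06). It passed as lower with the non-myocyte score (−0.85, 3.08e-16), with DESeq2 (−0.43, 0.000533) and without mouse 21A4 (−0.56), 21A5 (−0.58) or 21A7 (−0.50, 0.000294). The same held without the GFP− library of 21A4, 21A5 or 21A7 (−0.52, −0.62 and −0.75) or the GFP+ library of 17C1 or 17C2 (−0.47 and −0.59). Without the GFP− library of 17C1 its median was −0.067 and did not pass. When scaled to sarcomere genes its own median was −0.45, which is 0.48 above that of all genes. The test there was downward and did not pass (camera adjusted p = 0.0923).

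Several housekeeping groups stood slightly higher in GFP+ cells, although the proteasome and ribosome lists did not pass once the non-myocyte score was a covariate. The median of 34 proteasome subunit genes stood 0.39 above all genes (camera adjusted p = 7.88e-05; adjusted p = 0.674 with an estimated correlation), and their mean rise per mouse was 0.40 ± 0.12 (SD, n = 5). It was 0.36 in the 17C (camera adjusted p = 0.0229) and 0.51 in the 21A mice (5.17e-07), but 0.066 with the non-myocyte score (0.205). No member passed in either edgeR fit, and 0 unpaired and 5 paired did when adjusted over the list alone. Fry passed for this list with pairing (adjusted p = 0.0274; 0.555 unpaired). For 74 ribosomal protein genes, whose near-identical pseudogenes make their counts uncertain, the median stood at 0.51 (camera adjusted p = 9.81e-08; adjusted p = 0.696 with an estimated correlation), at 0.62 in the 17C (2.95e-10) and 0.28 in the 21A mice (0.000200). With the non-myocyte score it was 0.17 (0.0625), and without the GFP+ library of 17C1 0.34. For 20 tubulin and microtubule genes it stood at 0.52 (0.00183; adjusted p = 0.655 with an estimated correlation), at 1.36 in the 17C (1.24e-09) and 0.28 in the 21A mice, where it did not pass (0.142). Over single omissions the tubulin list passed each time, between 0.24 without mouse 17C1 and 0.94 without the GFP− library of 21A7. No ribosomal or tubulin gene passed over all 5 mice, but 15 ribosomal and 11 tubulin list genes passed as higher in the 17C mice. Of the tubulin list 3 were higher and 1 lower in the paired fit when adjusted over the list alone. The 23 antioxidant genes had a median of 0.19 (camera adjusted p = 0.0105; adjusted p = 0.545 with an estimated correlation). It was 0.31 in the 17C (0.0170, 5 members higher and 2 lower) and 0.31 in the 21A mice, where it did not pass (0.0712). Nor did it pass with library size alone (0.0854) or scaled to sarcomere genes (0.16 with an own median of −0.77, 0.0508). Over single omissions it lay between 0.10 without mouse 21A5 and 0.40 without the GFP− library of 17C1. Gpx3, the plasma glutathione peroxidase, was their 1 paired call (1.95 ± 0.33, edgeR adjusted p = 0.0434; 0.166 unpaired), and 2 unpaired and 5 paired passed when adjusted over the list alone. In the list of cornified envelope and Sprr family genes other than Sprr1a, 8 genes were tested, with a median 1.56 above all genes (camera adjusted p = 1.01e-07; adjusted p = 0.416 with an estimated correlation). It was 3.17 in the 17C (5 members higher) and 1.29 in the 21A mice, passing in both. When scaled to sarcomere genes it passed over all mice as higher than all genes (0.60), though its own median was −0.32. Relative to the sarcomere list it was higher in 4 of 5 mice and at −1.02 in 21A7. The rise of this list was largest in 17C1 (mean 4.42 log2 units) and smallest in 21A7 (0.59), as was that of the mesothelial markers (6.39 and 0.84). Krt18, a keratin that mesothelial cells also make, was the 1 paired call in it, and 3 unpaired and 4 paired passed when adjusted over the list alone. Transglutaminase Tgm2 was higher in 5 of 5 mice (2.13 ± 0.39, paired adjusted p = 0.0532; 2.62 in the 17C mice, 0.00167). Sprr2a3, whose near-identical copies make its counts uncertain, was at 2.93 ± 0.60 against 0.134 ± 0.299 CPM (paired adjusted p = 0.100; 0.0226 in the 17C mice).

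Other stress and survival lists did not pass as groups over all 5 mice, though several did within 1 series. Their camera adjusted p was 0.198 for hypoxia, 0.229 for heat shock, 0.744 for the unfolded protein response, 0.815 for interferon response, 0.380 for p53 and apoptosis and 0.815 for anti-apoptotic genes. It was 0.678 for autophagy, 0.661 for gp130 and STAT3, 0.214 for YAP targets and 0.414 for regeneration-associated genes. In the 17C mice the interferon (median 1.00, camera adjusted p = 0.0115), p53 (0.69, 0.0165), regeneration (0.33, 0.00537) and YAP lists (0.011, 0.0104) passed as higher. Of their members 0, 2, 5 and 6 passed there as higher and 1 regeneration gene as lower. The 5 regeneration genes include Sprr1a, the gene of the reporter, so this list's result is partly set by the sort. It was not tested without Sprr1a. In the 21A mice the hypoxia (0.32, 0.0449) and autophagy lists (0.48, 0.0378) passed as higher. With the non-myocyte score the interferon (0.94, 6.74e-05), YAP (0.30, 0.000367) and regeneration lists (0.42, 0.0384) passed as higher, the last again with Sprr1a (6.30) among its genes. Without the GFP− library of 21A7 the interferon list was at 0.56 (0.0326) and the YAP list at 0.031 (0.0221). The YAP list also passed, with an upward test, without the GFP− library of 21A5 (−0.12, 0.0482) or the GFP+ library of 17C1 (−0.053, 0.0418) or 17C2 (0.055, 0.0401). The hypoxia list passed without the GFP− library of 17C2 (0.42, 0.0340), and without the GFP+ library of 21A7 both it (0.27, 0.0361) and the heat shock list did (0.25, 0.0461). With voom the hypoxia list was higher (0.42, 0.0347) and the interferon list lower (−0.46, 0.0328).

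Single members of these lists did pass in the paired fit. The small heat shock protein Hspb1 rose by 1.65 ± 0.24 (edgeR adjusted p = 0.0318; 0.173 unpaired). Among YAP targets Tgfb2, a TGF-beta ligand, rose by 2.74 ± 0.47 (0.0434; 0.0765 unpaired) and Nt5e, an ectonucleotidase, by 1.79 ± 0.28 (0.0376; 0.0777 unpaired). With Ankrd1, 3 YAP targets passed paired and 0 unpaired, and 3 in each fit when adjusted over the list alone. The YAP and regeneration lists had medians below all genes (−0.14 and −0.29) but mean log2 fold changes above 0 (0.06 and 0.24) and an upward test. The regeneration list includes Sprr1a (6.09), the gene of the reporter, so its mean and test are partly set by the sort. The interferon list had a median of 0.02 above all genes, a mean of −0.09 and an upward test. Anti-apoptotic Bcl2l1 (0.20 ± 0.25, 0.857) and Birc2 (−0.59 ± 0.40, 0.727) did not pass. Cell cycle genes had a median of −0.58 (29 genes, camera adjusted p = 0.0567), at 0.39 in the 17C (0.375) and −0.80 in the 21A mice, where they passed as lower (5.03e-05). With the non-myocyte score it was 0.66 (0.0869). The list passed as lower with DESeq2 (−0.58, 0.0212) and voom (−1.31, 7.99e-06), without mouse 17C1 (−0.71), 17C2 (−0.59) or 21A7 (−0.74, 0.0406), and without the GFP− library of 17C1 (−0.77) or 17C2 (−0.76) or the GFP+ library of 21A7 (−1.27). Without the GFP− library of 21A7 its median was 0.080. With pairing it was −0.36 (camera adjusted p = 0.00904; adjusted p = 0.739 with an estimated correlation), with 1 lower call, and 3 when adjusted over the list alone. That call, the kinetochore gene Cenpf, was at −2.38 ± 0.38 (0.0376; 0.636 unpaired).

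Markers of other heart cells and matrix genes stood lower in GFP+ libraries over the 5 mice. In 17C1, 21A4 and 21A5 all 5 lists changed in the direction of the fibroblast share, which holds the fibroblast list's own genes. In 17C2 the share rose from 0.0978% to 0.123%, but the endothelial (−1.24), mural (−3.06) and macrophage (−0.67) list means fell on the log2 scale. In 21A7 the share fell from 5.20% to 2.18% and the mural list mean rose by 0.50. This co-movement was not tested. The median of 17 fibroblast genes was −1.28 relative to all genes (camera adjusted p = 0.000407; adjusted p = 0.674 with an estimated correlation), at 0.90 in the 17C (0.403) and −1.65 in the 21A mice. For 20 macrophage genes it was −1.48 (5.34e-05; adjusted p = 0.674 with an estimated correlation), at 0.011 in the 17C (0.729) and −1.76 in the 21A mice. For 18 endothelial genes it was −1.01 (0.000135; adjusted p = 0.674 with an estimated correlation), at −0.67 (0.375) and −1.10. For 10 mural genes it was −1.29 (0.0310; adjusted p = 0.696 with an estimated correlation), at −0.87 (0.670) and −1.30. For 28 matrix genes it was −1.41 (0.00252; adjusted p = 0.863 with an estimated correlation), at 0.62 (0.00353, 6 members higher) and −1.56. All 5 lists passed as lower in the 21A mice. With the non-myocyte score, which is made from the first 4 of these lists, these 4 did not pass (0.67, −0.062, −0.16 and −0.51) and the matrix list passed as higher (0.75, 3.81e-05). The matrix list did not pass without mouse 21A5 (−1.11, 0.135), the GFP− library of 21A5 (−1.01, 0.236) or 21A7 (−0.90, 0.255) or the GFP+ library of 17C2 (−1.13, 0.0528). The mural list did not pass without mouse 17C2 (−1.22), 21A4 (−1.21) or 21A5 (−0.86), the GFP− library of 21A4 (−1.09) or 21A5 (−0.68) or the GFP+ library of 17C2 (−0.998), with adjusted p of 0.0773 to 0.271. The macrophage list was −0.97 without the GFP− and −2.54 without the GFP+ library of 21A7, past the threshold in both, and without the latter the fibroblast list was −2.08 and the matrix list −2.14. None of these genes passed in the unpaired edgeR fit over all 5 mice. In the paired fit the complement gene C1qc (−1.91 ± 0.34, edgeR adjusted p = 0.0480), the TGF-beta coreceptor Eng (−1.57 ± 0.28, 0.0452), the endothelial phosphatase Ptprb (−1.58 ± 0.27, 0.0426) and the small proteoglycan Ogn (−1.65 ± 0.30, 0.0480) were lower. Paired and adjusted over the list alone, 2 fibroblast, 6 macrophage, 4 endothelial, 3 mural and 3 matrix genes were lower and 1 mural gene higher. Among paired calls with a mean of at least 10 CPM the largest falls were those of Cilp, a cartilage matrix protein (−2.89 ± 0.34, 0.0206), and Cybb, a phagocyte oxidase subunit (−2.45 ± 0.43, 0.0461). Igf1 (−1.88 ± 0.28, 0.0345), Sparcl1 (−1.84 ± 0.28, 0.0373), Ece1 (−1.67 ± 0.26, 0.0373) and Ltbp4 (−1.67 ± 0.28, 0.0426) were also lower in 5 of 5 mice. None of these falls passed unpaired (adjusted p 0.128 to 0.689).

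Immediate early genes, which tissue dissociation can raise, had a median of −0.87 (22 genes, camera adjusted p = 0.000722; adjusted p = 0.696 with an estimated correlation), at 0.38 in the 17C (0.495) and −0.97 in the 21A mice (6.72e-08). The list did not pass with the non-myocyte score (−0.11, 0.626) or without the GFP− library of 21A7 (−0.42, 0.245), and was −0.56 without that mouse (0.0245). No member passed over all 5 mice, and 0 unpaired and 6 paired were lower when adjusted over the list alone. Dusp1 was lower in 5 of 5 mice (paired −1.28 ± 0.26, edgeR adjusted p = 0.0737) and passed in the 17C mice (−1.56, 0.00558). Mitochondrially encoded protein genes, which have nuclear copies that make their counts uncertain, had a median of 2.68 (11 genes, camera adjusted p = 2.36e-05; adjusted p = 0.655 with an estimated correlation), at −1.15 in the 17C mice, where 6 passed as lower (camera adjusted p = 0.000913), and 4.19 in the 21A mice (5.00e-11). Without mouse 21A7 it was 0.73 and did not pass (0.177), and without the GFP+ library of that mouse it was 1.04 (0.0151). Of the Schwann cell and mesothelial list 5 genes were tested, all mesothelial, with a median of 1.497 (camera adjusted p = 0.000297; adjusted p = 0.655 with an estimated correlation). It was 4.35 in the 17C (1.58e-05) and 1.04 in the 21A mice, where it did not pass (0.0712). Over single omissions it passed each time, between 0.89 without the GFP+ and 2.98 without the GFP− library of 21A7. No member passed in either edgeR fit over all 5 mice, 4 passed as higher in the 17C mice, and 0 unpaired and 4 paired did when adjusted over the list alone. Atrial and conduction markers did not pass (12 genes, −0.39, 0.496).

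**Figure D3:**
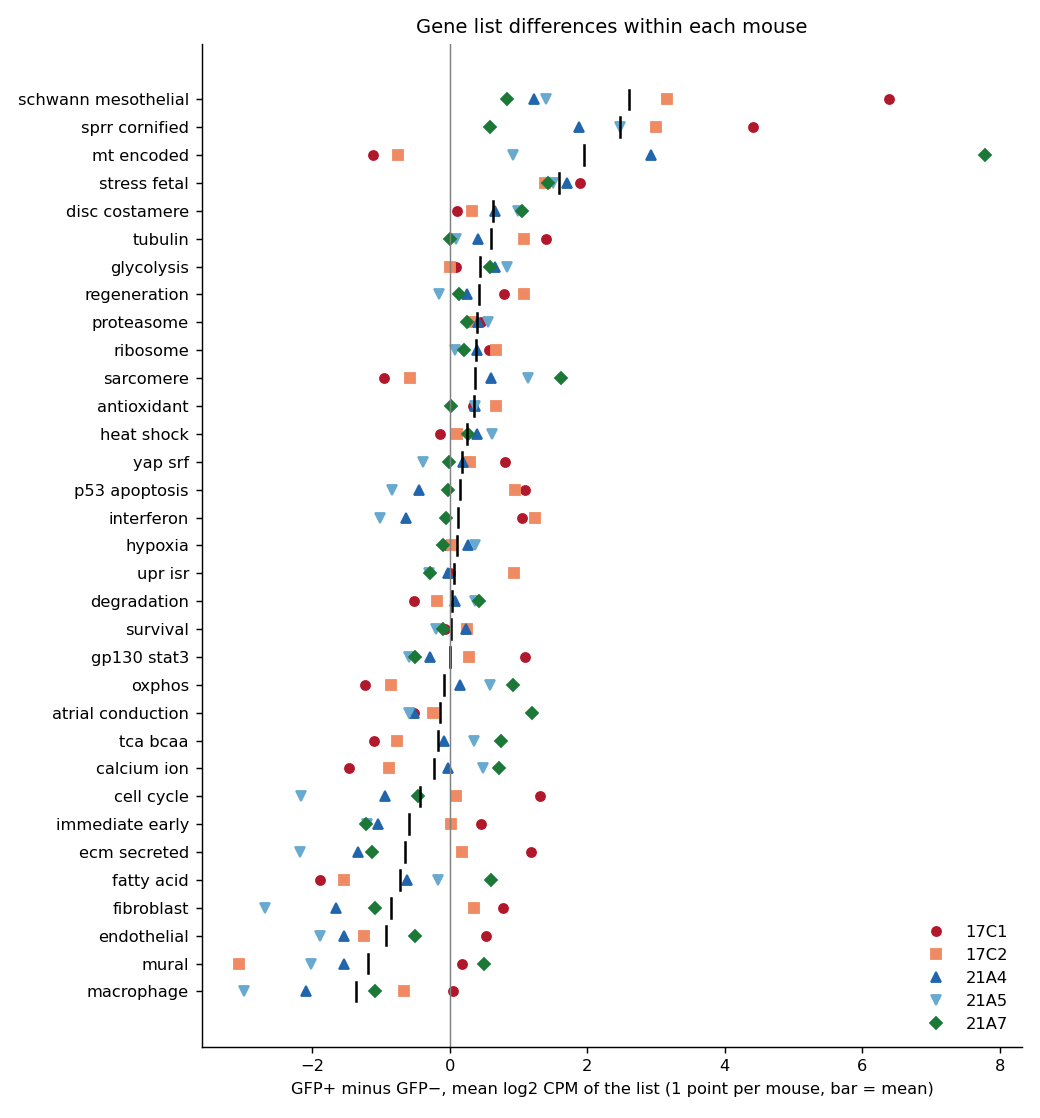
Difference between the GFP+ and GFP− library of each mouse in the mean log2 CPM of 33 gene lists, with 1 point per mouse and a bar at the mean of 5 mice; values are not taken relative to all genes. The fetal and stress list (stress fetal) lies between 1.39 and 1.89 in all 5 mice (relative to the sarcomere list it is below 0 in 21A7), while the sarcomere, fatty acid, respiratory chain (oxphos) and fibroblast lists have mice on both sides of 0.

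Over all 33 tested lists 17 passed with the preset correlation (10 higher, 7 lower) and 19 with pairing (11 and 8). With an estimated correlation 0 passed unpaired and 1 paired, and with fry 1 and 2. Within a series no list passed with an estimated correlation (adjusted p of 0.426 or more in the 17C and 0.480 or more in the 21A mice with an estimated correlation). By their titles the GFP+ libraries combine DAPI-negative and DAPI-positive gates and the GFP− libraries hold only DAPI-negative ones, DAPI being a dye that enters cells with leaky membranes. The sort by GFP and the gate by DAPI therefore cannot be told apart in these libraries.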

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

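The tests of RNA from other cell types, of genes made by the myocytes, of library batches, of dilution and of a shared fall of myocyte genes were chosen after the results were seen, as was the comparison of effects between the 2 series of mice; the thinning test and the counts of other splits were set before their results.

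Of 148 checks for a library far from the other 4 of its group, 11 found one, where chance gives about 1 in 20. The value given is the gap to the nearest library divided by the range of the group. In 10 of them the library was from mouse 21A7. Its GFP− library was lowest for Acta1 (0.852), Prnp (0.739) and the disc and costamere list (0.844). Its GFP+ library was lowest for Rtn4 (0.775), Prnp (0.730), the TCA and branched-chain amino acid list (0.752), the respiratory chain list (0.761) and the glycolysis list (0.729). It was highest for the fibroblast share (0.724) and the interferon list (0.792). The GFP+ library of 17C1 was lowest for the atrial and conduction list (0.766).

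The GFP+ against GFP− difference differed between the 21A and the 17C mice for 23 of 33 lists in a camera test of the interaction with a preset correlation. With an estimated correlation 0 lists passed (smallest adjusted p = 0.541). With edgeR 0 of 12115 genes passed unpaired (1713 at an unadjusted p under 0.05) and 923 with the mouse block. The median difference, 21A minus 17C on the log2 scale, was 5.34 for mitochondrially encoded genes, 1.74 for sarcomere, 1.45 for respiratory chain, 1.32 for calcium handling and 1.28 for fatty acid genes. It was 1.08 for TCA cycle, 1.08 for glycolysis, 0.88 for disc and costamere and 0.55 for autophagy genes. It was −2.91 for mesothelial, −2.73 for cornified envelope, −2.65 for fibroblast, −2.01 for matrix, −1.76 for macrophage, −1.42 for cell cycle and −1.40 for interferon genes. It was −1.35 for immediate early, −1.19 for p53, −1.06 for tubulin, −0.77 for gp130, −0.72 for regeneration-associated, −0.68 for endothelial and −0.39 for ribosomal protein genes.

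Non-myocyte markers were lower in the GFP+ libraries of the 21A mice. After thinning the remaining counts of every library to 2217409, the median fibroblast difference in these mice was −1.83 (upper quartile of members −1.52). Thinning leaves each gene's expected share of the counts unchanged, so it could hardly have moved this difference whatever the cause. The thinning test therefore cannot decide whether fewer remaining counts in GFP+ libraries play a part. Matrix and vessel genes made by the myocytes themselves would leave macrophage genes alone, but within the 21A mice these had a median difference of −2.17 (upper quartile of members −1.83, list mean −2.99 to −1.09 per mouse), so this source stays open only for the fibroblast and endothelial genes, at −1.52 in these mice, which no value here decides. A candidate explanation is RNA of other cell types in the 21A GFP− libraries, since the smallest of the fibroblast, macrophage and endothelial list medians was 2.62 higher there than in the 17C GFP− libraries, while the sarcomere median was −1.82; the sort for cardiomyocytes would be meant to remove such cells. A difference between library batches cannot be told apart from one between the animals, because each mouse belongs to 1 series, and fibroblast genes were also 2.13 higher in the 21A than in the 17C GFP+ libraries.

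Fatty acid genes were lower in GFP+ libraries in the 17C mice and less so in the 21A mice. Relative to the sarcomere list the fatty acid list was lower in 5 of 5 mice, by a mean of −1.09 ± 0.17 (SD, exact sign-flip p = 0.0625, the smallest that 5 mice allow, 0.5 after adjustment over 32 lists). In these libraries the 2 lists thus did not change by the same amount. The list medians had shown this before the scale was chosen, so it cannot decide whether all adult myocyte genes fell alike. The difference relative to the sarcomere list was −0.95 in the 17C and −1.18 in the 21A mice, −0.23 apart. Dilution of the 21A GFP− libraries by other cells may therefore account for the gap between the series in this list. The same scale did not bring the series together for the fetal and stress (2.41 in the 17C and 0.43 in the 21A mice), disc and costamere (0.99 and −0.22) or glycolysis list (0.82 and −0.42). A change in the sarcomere genes themselves and a difference between the animals stay open, as untested.

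Of 100 of the 126 splits of the 10 libraries, the real one included, 2 gave at least 10 genes, a share under 0.05. Chance can be excluded for the count of 10 only if the 10 libraries are taken as exchangeable, which libraries paired by mouse and grouped by series are not. The other split gave 1773 genes, parted 1 of 5 mice and put 4 libraries of the 17C series on one side, which points to a structure of the samples. Another of the drawn splits with that make-up gave 0 genes, so the structure was not shown to be the series. With the series as a covariate 97 genes passed. Within the 16 splits that part all 5 mice the real one gave 10 genes unpaired and 104 paired and the highest other 0 and 0. These 16 splits are too few for a share under 0.05.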

How the results depend on the processing

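Among these alternatives the non-myocyte score, scaling to sarcomere genes, removal of 5 abundant loci and all alternatives of the paired fit were chosen after seeing the data. The Sprr1a log2 fold change was above 0 in all 29 alternatives and passed in 16, with adjusted p from 1.05e-14 to 0.603. The fetal and stress list was higher and passed in each of these 29, and with fry. With an estimated correlation it passed in the paired fit (adjusted p = 0.0383 with an estimated correlation) but not unpaired (0.0639). The number of genes past the threshold moved, and except where fewer libraries or genes were tested the cause was not tested. Against 10 genes unpaired (10 higher, 0 lower), the replicate block by mouse gave 104 (83 higher, 21 lower), library size alone 635 (624 lower), no filter on low counts 38 (38 higher) and a stricter filter 19 (18 higher, 1 lower). DESeq2 gave 205 (160 higher, 45 lower), voom 336 (285 higher, 51 lower), the series as a covariate 97 (77 higher, 20 lower), the 17C mice 1059 (512 higher, 547 lower) and the 21A mice 0 (0 higher). The non-myocyte score as a covariate gave 45 (43 higher, 2 lower) and scaling to sarcomere genes 0 (0 higher). DESeq2 size factors and removal of mitochondrial genes, with or without 5 abundant loci, gave 10 each. Leaving out a mouse or a library gave 0 to 58 genes, all higher: 58 without mouse 21A7, 34 without its GFP+ library, and 0 without any other mouse (566 to 893 at an unadjusted p under 0.05). The 104 paired calls became 889 in the 21A mice, 1510 in the 17C mice, 33 with library size alone, 818 with no filter, 1163 with voom, 0 with scaling to sarcomere genes (1124 at an unadjusted p under 0.05) and 0 to 173 without 1 mouse. The Sprr1a log2 fold change was 5.999 in the 21A mice (edgeR adjusted p = 0.203), 5.11 with scaling to sarcomere genes (0.603) and 5.75 to 6.85 when a mouse or library was left out. The 17 lists became 0 with an estimated correlation, 1 with fry and 18 with ranks, and 15 to 21 under the others. Among the preset genes and the lists, pairing changed no call other than those given with both values in the report.

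Some list medians changed sign. In the 17C mice they were −0.018 for disc and costamere, −0.89 for sarcomere, −0.26 for glycolysis, 0.011 for YAP targets, 0.33 for regeneration-associated, 0.39 for cell cycle, 0.62 for matrix and 0.38 for immediate early genes. There they were −1.15 for mitochondrially encoded, 0.90 for fibroblast and 0.011 for macrophage genes, and mt-Nd4 was at −1.17. In the 21A mice they were 0.55 for calcium handling, 0.26 for TCA cycle and 0.45 for respiratory chain genes. With the non-myocyte score as a covariate they were −0.15 for sarcomere, 0.30 for YAP targets, 0.42 for regeneration-associated, 0.66 for cell cycle, 0.75 for matrix and 0.67 for fibroblast genes. With that covariate the glycolysis, proteasome, ribosome, immediate early, macrophage, endothelial and mural lists kept their sign but no longer passed. The last 3 are part of the score. With scaling to sarcomere genes the TCA list was at 0.37, and the calcium handling and respiratory chain lists at 0.48 each, relative to all genes, whose median was −0.93. Their own medians were −0.56, −0.44 and −0.45 with downward tests, so on the sarcomere scale itself they stayed below 0. The interferon list was at −0.46 with voom. Without single libraries the YAP list lay between −0.32 and 0.055, above 0 without the GFP− library of 21A7 or the GFP+ library of 17C2. Depth limits low genes most, with 2217409 counts left for nuclear genes in the GFP+ library of 21A7.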

Other observations

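The test of a general difference in the share of other cells and the values relative to the sarcomere list were chosen after the results were seen, while the second list of mesothelial genes was written before its values were looked at. Genes of mesothelial and other lining cells stood higher in GFP+ libraries. Upk3b, a uroplakin, was at 37.2 ± 21.6 against 8.58 ± 11.9 CPM (SD, n = 5; paired log2 fold change 2.86 ± 0.86, edgeR adjusted p = 0.180). Upk1b was at 18.9 ± 15.6 against 4.66 ± 6.25 CPM (2.49 ± 0.81, 0.203) and Lrrn4 at 20.9 ± 14.3 against 8.54 ± 11.9 CPM (2.13 ± 0.59, 0.148). Krt8, the partner of Krt18, was at 42.7 ± 34.7 against 8.73 ± 13.6 CPM (3.27 ± 0.77, 0.104). Each was higher in 5 of 5 mice and none passed the threshold over all 5 mice in either fit. Within the 17C mice all 4 passed unpaired, with log2 fold changes of 4.71 for Upk3b (edgeR adjusted p = 0.0208), 4.36 for Upk1b (0.0308), 3.80 for Lrrn4 (0.0246) and 5.32 for Krt8 (0.0179). In the 21A mice they were at 1.51, 1.47, 0.89 and 1.84 and did not pass (adjusted p 0.474 to 0.694).

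A candidate explanation for the mesothelial markers is RNA of mesothelial cells in the GFP+ libraries. In a second list of 11 mesothelial genes, 0 of them in another list used here, 10 were tested, with a median paired log2 fold change of 2.12, a score higher in 5 of 5 mice (mean 2.56 ± 2.05, SD) and 8 genes higher in all 5. The most abundant were Krt19 (47.1 against 7.95 CPM), Aldh1a2 (25.3 against 19.3 CPM, not higher in all mice), Gpm6a (23.0 against 6.48 CPM) and Krt7 (21.2 against 4.25 CPM), and none of these 4 passed the threshold over all 5 mice. In the 17C mice Krt19 (4.89, edgeR adjusted p = 0.0183), Aldh1a2 (3.43, 0.00476) and Krt7 (4.96, 0.0195) passed and Gpm6a did not (0.0715). A general difference in the share of other cells would move the mesothelial genes like the fibroblast, macrophage and endothelial lists. The mesothelial genes stood 3.65 ± 1.53 above those, between 1.73 and 5.93 per mouse (exact sign-flip p = 0.0625, the smallest that 5 mice allow). The opposite directions of these lists over the 5 mice were known when this comparison was chosen. It therefore restates that result and is no separate test of such a difference. Whether the GFP gate would remove such cells, and whether border zone cardiomyocytes make these transcripts themselves, was not tested and stays open.

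Relative to the sarcomere list, the scores of 3 lists besides the fatty acid list were lower in GFP+ libraries in 5 of 5 mice. Calcium handling genes were at −0.60 ± 0.22 (SD, n = 5), TCA cycle and branched-chain amino acid genes at −0.53 ± 0.34 and respiratory chain genes at −0.45 ± 0.18. Each had an exact sign-flip p of 0.0625, the smallest possible, and 0.5 after adjustment over 32 lists.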
